A study of Equus caballus with 10 samples.

How the data were processed

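Messenger RNA of whole blood was measured by RNA-seq in 10 Arabian horses, of which 6 were untrained and 4 were in racing training. Per the labels' protocols, total RNA was isolated with a magnetic-bead kit, its integrity was examined by tape and gel electrophoresis, and libraries were made with the TruSeq RNA Kit v2. Per the series' design text, libraries were read as 75-base single-end reads on an Illumina HiScan SQ in 6 technical repetitions. Whether the deposited counts sum these repetitions is not given in the sources used here. The submitters' processing notes list FastQC, STAR (a spliced-read aligner), RSEM (a transcript quantifier) and DESeq (a count test), without versions or roles. The genome build, the annotation release and the strand setting are not given in the sources used here.

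The deposited count table holds whole-number counts per row, not normalized, for 26991 Ensembl horse gene IDs and 555 repeat element names. The authors' deposited comparison table gives mean normalized counts, a signal made by dividing counts by size factors, for untrained horses, trained horses and all horses. The authors' deposited fold is the ratio of the trained to the untrained mean, and the authors' deposited log2 value is the log2 of that fold. The p-value and the adjusted p-value in the authors' deposited table go with DESeq, the only test that the submitters' processing notes list, and the method of adjustment is not given in the sources used here. Its group means were recomputed from the count table with median-of-ratios size factors and differed by at most 5.00e-12, which settled the direction of the fold. Its 2405 rows are the rows of the count table with a count of at least 2 in at least 1 library. A second deposited table holds the 6 rows of the first with an adjusted p under 0.05.

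The files give gene IDs without names. A horse reference gene table matched 0 of the IDs with counts, so no gene could be given a symbol, a function or a position. For this reason 28 gene lists fixed before the data were examined (among them bone, blood cell type, stress and energy metabolism lists) could not be tested, haemoglobin genes could not be left out, and the sex labels could not be checked on sex-linked genes. The rule for named genes was fixed at the same time. It took, among genes with a symbol, the 10 largest rises and 10 largest falls past the threshold, the leading members of each list, each gene of the authors' significant table, and the leading genes by p for sex and for the interaction. Without symbols, at most 2 IDs per direction are printed: the largest rises past the threshold, the largest fall past it, and the only gene that the authors' table called lower.

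Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM scaling) in R 4.3.3, after filterByExpr with its default minimum count of 10 and total of 15, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The filter left 968 genes, which held 96.8% of the counts. Standard errors of log2 fold changes were derived from the F statistic. Training was fitted without a covariate, sex with training as a covariate, and the interaction of the pair with both main effects. CPM values used TMM-scaled library sizes, and log2 CPM used a prior count of 2. Values of whole libraries were compared by exact two-sided permutation over all 210 splits of the 10 horses, with adjustment over 7 measures. The samples are different animals, so p-values measure the spread between horses. All 21 pairs of horses within a group differed by more than sampling noise (chi-square per degree of freedom 2.41 to 10.5), and none was treated as a duplicate.

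Library totals ran from 70899 to 129195 counts, with a median of 30 counts per tested gene and library. Counts were simulated with the real means and library sizes and the trended dispersion, with each gene drawn independently. Such counts hold no outlying horse and no shift shared across genes, so the rates may be better than in the real data. For training (973 genes tested), the test recovered 26.2% of 1.5-fold, 77.4% of 2-fold and 100% of 4-fold changes among changed genes past the filter. Of its calls, 3.82% were false. For sex (959 genes) it recovered 27.7%, 78.1% and 100% at the same folds. For the interaction (950 genes) it recovered 0%, 10.4% and 64.5%. Intervals and limits for a count of 0 cover counting error only.

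The alternatives tried were DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights), RLE size factors, no filter, a filter of CPM of at least 1 in at least 4 libraries, the 10 most abundant genes left out, sex as a covariate, each sex by itself, other thresholds, 1 surrogate variable (sva 3.50.0) and each horse left out in turn. The CPM filter had been meant as a stricter one, but at these totals it kept 2165 genes, more than the 968 of filterByExpr, so it is a looser one. A stricter filter (mean of at least 30 counts per library, 488 genes), robust moderation, no scaling factor, the trained males left out and the 37 highest-numbered IDs left out were added after the data were seen. Replicate numbers in the labels are not shared between groups, so no paired fit applied.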

Results

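Whole-blood transcript counts were available for 10 Arabian horses. The untrained group held 4 males and 2 females aged 2.5 years, and the trained group held 2 males and 2 females aged 3 years. The series title places the comparison in bone remodelling during race training. Age differed together with training, so every difference between the groups is one of training and age combined, and of anything else that went with the groups. Dates of sampling and sequencing and the time since the last exercise are not given in the sources used here. Horses are named by the sample numbers in the labels: 17, 49, 50, 51, 52 and 53 untrained, and 21, 31, 32 and 33 trained. Genes are known here only by Ensembl ID, so what they encode is not described.

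The libraries were shallow. Totals were 117252 ± 7901 counts (SD, n = 6) in untrained horses and 102466 ± 21402 (SD, n = 4) in trained horses, and the lowest was 70899 in trained horse 33. Of 26991 gene rows, 4213 (15.6%) had a count in any library and 1278 had one in all 10. Another 1258 genes had a single count over the whole series. A library showed counts for 1762 to 2384 genes. After random thinning to 50% of the counts, 82.4% to 85.3% of the genes of a library were still seen. The 10 most abundant genes took up to 37.7% of a library, and the 2 most abundant averaged 8341 and 8251 counts per library. None of the 555 repeat element rows had a count in any horse. Whether reads were counted on these rows is not given in the sources used here. Only if they were does the count of 0 allow a share, of at most 0.00232% to 0.00423% of a library's counts.

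The trained males stood apart from the untrained horses in general profile. The first principal component of log2 CPM over 968 genes held 41.8% of the variance. Its score was -6.03 ± 1.35 (SD, n = 6) in untrained horses and 9.04 ± 10.1 (SD, n = 4) in trained horses, a difference of 15.1 (exact permutation p = 0.00476, adjusted p = 0.0333, 7 measures), where 0.00476 is the smallest p that 210 splits can give. Trained males 21 and 33 scored 20.4 and 14.0, trained females 32 and 31 scored 3.84 and -2.09, and the highest untrained horse, 17, scored -3.66. On average, log2 CPM of horse 21 correlated with that of untrained horses at r = 0.867 and that of horse 33 at r = 0.890, against 0.939 for horse 31 and 0.930 for horse 32. Untrained horses correlated with each other at a mean r of 0.927 to 0.948, a range that holds both trained females. Horse 31 correlated less with the other trained horses (r = 0.919) than with untrained horses. These are correlations across genes, which are not independent replicates.

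**Figure D1:**
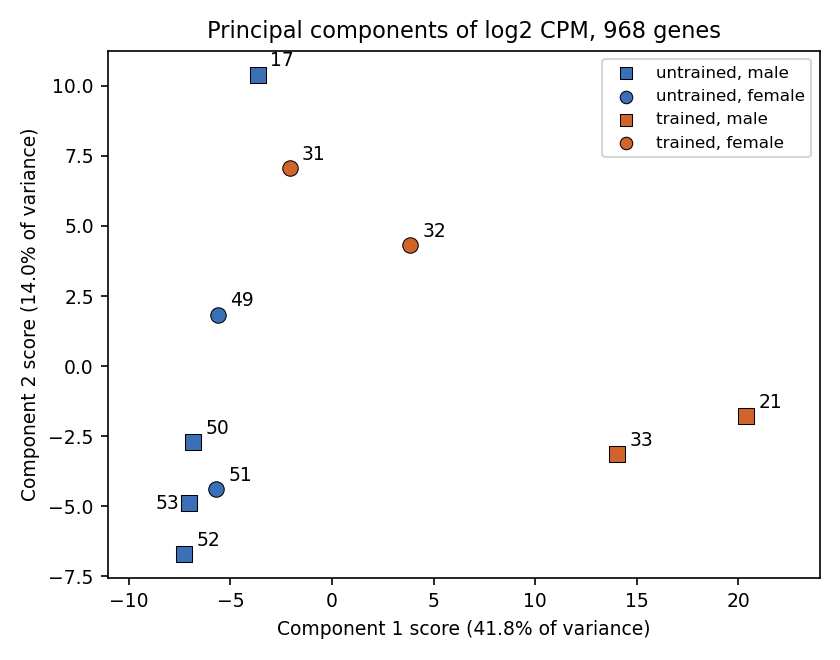
Scores of the 10 horses on the first (x axis) and second (y axis) principal component of log2 CPM, without unit, with colour for training and marker shape for sex. The trained males 21 and 33 lie to the right at 20.4 and 14.0, and the 6 untrained horses lie between -7.30 and -3.66 on the first component.

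Library measures shifted in the same horses without a difference between groups that passed adjustment. The share of counts in the 10 most abundant genes was 34.4% ± 3.12 (SD, n = 4) in trained and 31.5% ± 0.969 (SD, n = 6) in untrained horses (exact permutation p = 0.0667, adjusted p = 0.128). It was 37.7% in horse 21 and 36.2% in horse 33. TMM factors were 0.942 ± 0.0936 in trained and 1.04 ± 0.0416 in untrained horses (exact permutation p = 0.0381, adjusted p = 0.128). After every library was thinned to 70899 counts, 1860 ± 136 genes were seen in trained horses and 1979 ± 52.2 in untrained horses (exact permutation p = 0.10, adjusted p = 0.128). Horses 21 and 33 were lowest, at 1738 and 1762 genes. Trained females 32 and 31 showed 1908 and 2030, and untrained horses 1897 to 2026.

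The first comparison asked which genes differed in blood between trained and untrained horses. Of 968 genes tested, 16 were higher and 9 were lower in trained horses at an adjusted p under 0.05 (edgeR quasi-likelihood test). Rises ran from 0.66 to 2.08 on the log2 scale, with a median of 0.89, and falls ran from -0.96 to -1.99, with a median of -1.56. The genes that rose were the more abundant, with a median of 60.4 counts per library against 22.0 for those that fell. The median over all tested genes was 30.3. With the calls included, 249 genes had an unadjusted p under 0.05, of which 130 were higher and 119 lower, where 48.4 were expected by chance. With 1 horse left out, this count was 327 without trained horse 31 and 283 without untrained horse 17. It was 157 without trained horse 21, and up to 233 without each of the other horses. It was 128 without both trained males and 105 with 1 surrogate variable. The fits with horses left out tested 949 to 1066 genes on fewer horses. In 70 genes the CPM ranges of the groups did not overlap, 37 with trained horses above and 33 below, against 9.22 expected by chance (0.952%). They included 12 of the 16 genes that rose and 8 of the 9 that fell. The chance counts of 48.4 and 9.22 are averages. Genes are not independent, and how far such counts vary by chance was not measured.

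The largest rise was in ENSECAG00000008639, which went from 160.1 ± 59.4 CPM (SD, n = 6) in untrained to 696 ± 303 CPM (SD, n = 4) in trained horses. Its log2 fold change was 2.08 (SE 0.288, edgeR adjusted p = 0.00106), and the lowest trained horse, at 395 CPM, was above the highest untrained horse, at 258 CPM. ENSECAG00000018638 rose from 129.6 ± 37.7 to 330.0 ± 162 CPM, a log2 fold change of 1.39 (SE 0.297, edgeR adjusted p = 0.0230). Its highest untrained horse, at 198 CPM, lay just below its lowest trained horse, at 204 CPM. Its unscaled counts overlapped, with 11 to 24 in untrained and 13 to 66 in trained horses. The largest fall was in ENSECAG00000014950, from 120.0 ± 28.3 to 28.9 ± 14.8 CPM, a log2 fold change of -1.99 (SE 0.397, edgeR adjusted p = 0.0224). This last gene was thinly counted, with 10 to 18 counts in untrained and 1 to 4 counts in trained horses. ENSECAG00000018638 missed the threshold without trained horse 32 (edgeR adjusted p = 0.0604), without horse 33 (0.0543), without scaling factors (0.0535), in females (0.0904) and in males (0.239). Its log2 fold change was 1.38, 1.51, 1.26 and 1.89 in the first 4 of these fits and 0.67 in males. ENSECAG00000014950 missed it without horse 32 (edgeR adjusted p = 0.0530), without horse 33 (0.0819), in males (0.0639), in females (0.196), with 1 surrogate variable (0.167) and without both trained males (0.178), while its log2 fold change stayed between -1.86 and -2.17. ENSECAG00000008639 missed it in females, at a log2 fold change of 1.40 (SE 0.367, edgeR adjusted p = 0.169). The authors' deposited table did not call ENSECAG00000014950 either, at a log2 value of -2.04 and an adjusted p of 0.150.

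**Figure D2:**
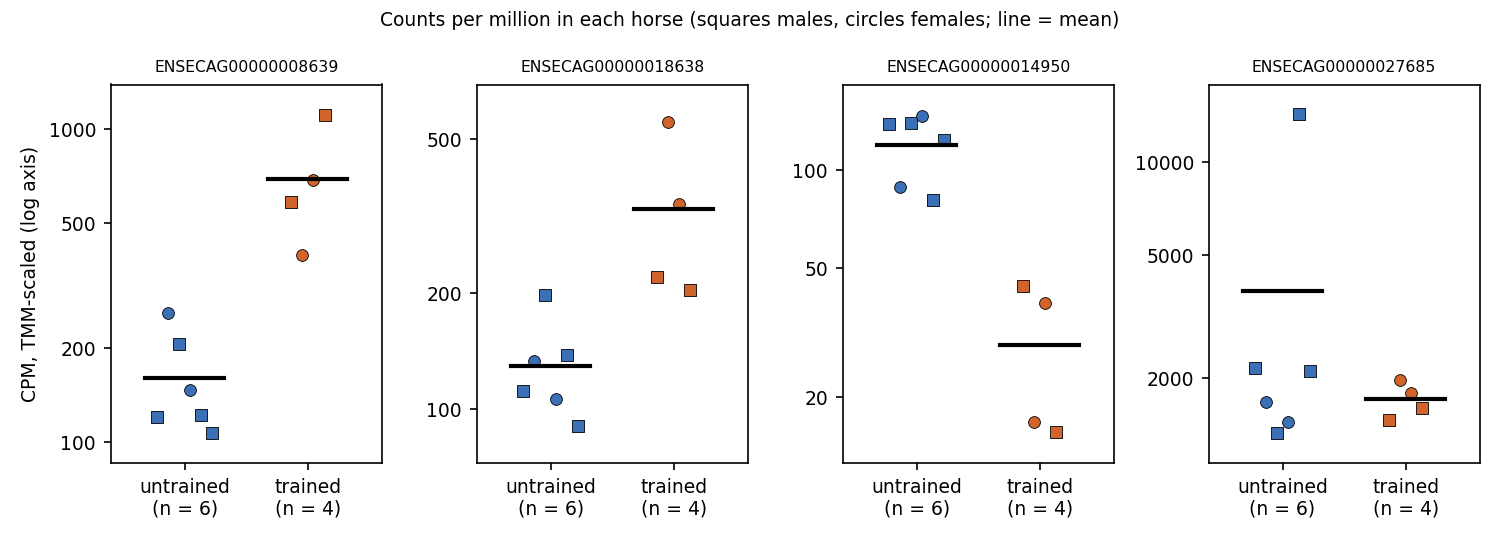
CPM on logarithmic y axes for 4 genes in untrained (blue, n = 6) and trained (orange, n = 4) horses, with squares for males, circles for females and a line at each group mean. The groups do not overlap in TMM-scaled CPM in the first 3 genes, though only narrowly in ENSECAG00000018638 (198 against 204 CPM). In ENSECAG00000027685 the untrained mean of 3832 CPM lies above 5 of the 6 untrained horses because horse 52 is at 14278 CPM.

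The number of genes called rested on single horses. Leaving out 1 horse at a time gave 86 calls without untrained horse 17, 9 without horse 50, 14 without horse 52, 16 without horse 53, 7 without trained horse 21, 97 without horse 31, 2 without horse 32 and 1 without horse 33. Between 1 and 25 of the 25 called genes stayed past the adjusted threshold in these fits. Their log2 fold changes kept their sign and at least 0.720 of their size, with unadjusted p up to 0.00675, although the genes had been chosen on mostly the same horses. With library totals in place of TMM, the calls split into 7 higher and 12 lower (36.8% higher, against 64% with TMM), and the median log2 fold change of all tested genes moved from 0.00 to -0.15. Without trained males 21 and 33, 2 genes were called, both higher in trained horses. No filter on low counts gave 76 calls, in a fit that gave no weight to a gene's own variance. DESeq2 gave 60 calls and 1 surrogate variable gave 2. That variable was not separate from training, with values of 0.806 and 0.359 in trained males 33 and 21, -0.00817 and -0.213 in trained females 32 and 31, and -0.279 to -0.0691 in untrained horses.

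**Figure D3:**
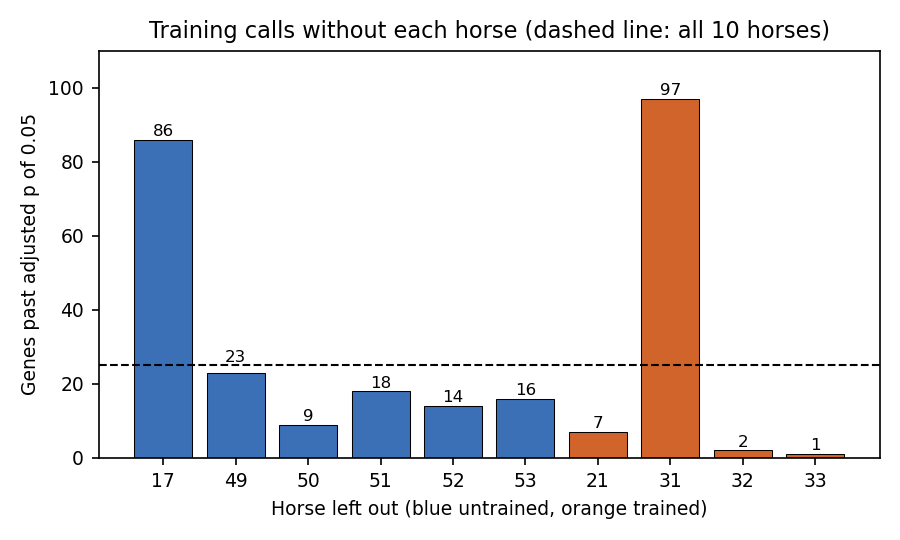
Bars give the number of genes past an adjusted p of 0.05 for training (y axis) when the horse on the x axis is left out, in blue for untrained and orange for trained horses, and the dashed line marks the 25 calls with all 10 horses. The count rises to 86 and 97 without horses 17 and 31 and falls to 2 and 1 without trained horses 32 and 33.

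The authors' deposited table of 2405 genes called 6 genes at an adjusted p under 0.05, of which 5 were higher and 1 was lower in trained horses. The folds of the 5 higher genes in that table ran from 1.74 to 4.42. All 5 were also called higher by edgeR here, and the other 20 calls of edgeR are not among the authors' 6. Of the authors' 6, edgeR called 2 without trained horse 32, 1 without horse 33, 2 without both trained males, 2 with 1 surrogate variable, 3 at a log2 fold change of at least 1 and 0 in females. Log2 fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.997 and a Spearman rho of 0.997 across the 968 genes, which share the same counts, and 949 genes had the same sign. In the authors' deposited table, 206 genes had an infinite log2 fold change because 1 group had no counts, and 637 had a mean normalized count under 1.

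The gene that the authors' deposited table called lower was ENSECAG00000027685, with mean normalized counts of 399 in untrained and 179 in trained horses, a fold of 0.448 and an adjusted p of 0.0411. edgeR gave it a log2 fold change of -1.17 (SE 0.563, adjusted p = 0.200), so it was not called here. Untrained horses had 3832 ± 5129 CPM (SD, n = 6) and trained horses 1706 ± 220 CPM (SD, n = 4). Horse 52 had 1759 counts of this gene, 14278 CPM, while the next untrained horse had 2165 CPM. Without horse 52 the log2 fold change was -0.031 (SE 0.181, edgeR adjusted p = 0.939).

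The second comparison set the 6 males against the 4 females, with training as a covariate. No gene passed the threshold among 968 tested (edgeR, smallest adjusted p = 0.805), and 46 had an unadjusted p under 0.05, where 48.4 were expected by chance. Single horses moved this count, to 90 without horse 51, 70 without horse 17, 25 without horse 21 and 26 without horse 32. limma voom called 0 of the 968 genes, with 51 at an unadjusted p under 0.05. DESeq2, run on 4211 genes, called 0, with 39 at an unadjusted p under 0.05. Of those, 32 were among the 968 genes, where 48.4 were expected by chance. Of the 4213 genes with a count, 1258 had a single one, so no chance count is given for the wider set. With looser filters on low counts edgeR called 16 genes of 4213 (no filter) and 1 of 2165 (CPM of at least 1 in at least 4 libraries).

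The third comparison asked whether the training difference itself differed between males and females. No gene passed the threshold in the test of the interaction (edgeR, smallest adjusted p = 0.0905), and 150 of 968 genes had an unadjusted p under 0.05, where 48.4 were expected by chance. That count was 80 without horse 31, 87 without horse 21 and 99 without horse 51. It rose to 200 without horse 33 and 172 without horse 17, and was 136 to 150 without each of the others. These fits tested 949 to 1014 genes. limma voom called 0 of the 968 genes, with 159 at an unadjusted p under 0.05. DESeq2, run on 4213 genes, called 0, with 101 at an unadjusted p under 0.05. Of those, 84 were among the 968 genes, where 48.4 were expected by chance. As for sex, no chance count is given for the wider set. The 25 genes called for training were chosen on the males and females together, so their values in each sex are no separate test of direction. For the 16 that rose, the median log2 difference was 1.04 in males and 0.81 in females. For the 9 that fell, it was -1.73 in males and -0.95 in females. The trained minus untrained difference in mean log2 CPM was 2.43 in males and 1.34 in females for ENSECAG00000008639, and 0.64 in males and 1.72 in females for ENSECAG00000018638. Neither difference between sexes passed the threshold (edgeR interaction, adjusted p = 0.316 and 0.280). For ENSECAG00000014950 it was -1.57 in both sexes. Fitted by themselves, the 6 males gave 111 calls (43 higher, 68 lower) and the 4 females gave 0 calls with 122 genes at an unadjusted p under 0.05. Each sex had only 2 trained horses, and with looser filters the interaction gave 22 calls of 4213 genes (no filter) and 11 of 2165 (CPM of at least 1 in at least 4 libraries). The prior degrees of freedom were infinite and 47.7 in these fits, against 9.65 in the main fit.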

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

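The test of horse 52 was chosen after its value had been seen. Among 22 sets of values searched (11 measures in each of the 2 groups), 1 held a horse far from the others of its group. How often chance would flag such a set was not measured, and 1 flag among 22 sets may arise by chance. The flagged value was the CPM of ENSECAG00000027685 in untrained horse 52, at 14278 against 2165 in the next untrained horse, a gap of 0.935 of the group's range.

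The pattern is that the single gene called lower in trained horses by the authors' deposited table (adjusted p = 0.0411) has 1 untrained horse far above all the others. Without horse 52 the log2 fold change went from -1.17 (SE 0.563) to -0.031 (SE 0.181), within 2 standard errors of 0, so the fall rested on 1 library with a high value. Among females alone the difference was 0.25 (SE 0.183), within 2 standard errors of 0. Among males, with horse 52 among them, it was -1.69 (SE 0.802, edgeR adjusted p = 0.1745). Over all horses it was -0.814 (SE 0.601) with sex as a covariate and -0.445 with limma voom. edgeR without a filter on low counts called the gene at an adjusted p of 7.12e-06, and its standard error there was 0.204 against 0.563 with the filter. The prior degrees of freedom were infinite in that fit, against 9.72 with the filter, so the gene's own variance had no weight. The gene is 1 of the 37 highest-numbered IDs. Of the 35 of these with at least 10 counts in total, 2 had their highest CPM in horse 52, against 18 in horse 53 and 9 in horse 17. What raised the gene in horse 52 stays open, since the labels give nothing that sets this horse apart and no biological explanation was tested.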

How the results depend on the processing

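The settings named as added in this paragraph were chosen after the data were seen. The training count of 25 (16 higher, 9 lower) stayed within 1.5 times with RLE size factors (27), the 10 most abundant genes left out (30) and sex as a covariate (36, although the lower genes came to 16). It moved to 60 (36 higher, 24 lower) with DESeq2, 76 (35, 41) without a filter, 38 (23, 15) with the looser filter of CPM of at least 1 in at least 4 libraries (2165 genes tested, against 968), 77 (52, 25) with limma voom, 14 (6, 8) at a log2 fold change of at least 1, 104 (55, 49) at an adjusted p under 0.1, 111 (43, 68) in males, 0 (0 higher, 0 lower) in females and 2 (2, 0) with 1 surrogate variable. Of the 25 genes, 25 were kept without a filter, 24 with limma voom and 23 with DESeq2. Among added settings, leaving out the trained males gave 2 (2, 0), leaving out the 37 highest-numbered IDs 64 (36, 28), robust moderation 36 (20, 16), no scaling factor 19 (7, 12) and a stricter filter of a mean of at least 30 counts (488 genes tested) 22 (11, 11), of which 14 were among the 25; edgeR's sex and interaction calls stayed at 0 there, with 23 and 86 genes at an unadjusted p under 0.05. All 25 genes were also called with those 37 IDs left out and with robust moderation, where the prior degrees of freedom rose from 9.72 to 14.3 and 17.7. Leaving out each horse gave 1 to 97 calls, with 1 to 55 higher and 0 to 51 lower: 86 without horse 17, 9 without 50, 14 without 52, 16 without 53, 7 without 21, 97 without 31, 2 without 32 and 1 without 33; 23 and 18 without horses 49 and 51. Sex calls (0) moved to 16 without a filter and 1 with the CPM filter. Interaction calls (0) moved to 22 and 11 with those looser filters and to 0 to 2 with each horse left out, the 2 calls being without horse 17. ENSECAG00000027685 came to 0.25 (SE 0.183, adjusted p = 0.584) in females, of the other sign but within 2 standard errors of 0. ENSECAG00000008639 kept its direction under every setting run and missed the threshold only in females (adjusted p = 0.169). Filters also changed the prior degrees of freedom for training, from 9.72 to infinite without a filter and to 24.8 with the CPM filter. Without a filter a gene's own variance thus had no weight, and calls there can rest on 1 horse. Apart from the filters and subsets, which change the genes or horses tested, the cause was not tested. Depth limits the thin genes: the falling genes had a median of 22.0 counts per library, and 3245 genes with a count were below the filter. The alternatives planned for gene lists were not run, since no ID could be named.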

Other observations

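The comparison by sex on the first principal component was chosen after the result was seen. So were the tests of the highest-numbered IDs and of genes seen in 1 group. The 37 highest-numbered gene IDs held 9.54% to 19.8% of a library's counts, and 15 of them were among the 100 most abundant genes. Of the 35 with at least 10 counts in total, 18 had their highest CPM in untrained horse 53 and 9 in untrained horse 17. Their share did not differ between groups beyond the spread between horses (trained minus untrained -0.942 percentage points, exact permutation p = 0.662). In 4 genes, every untrained horse had a count and no trained horse had one, and 0 genes showed the opposite. The 4 genes summed to 8 to 14 counts over the untrained horses, 3 of the 210 splits gave as many such genes, and 0 genes were left when every library was thinned to the smallest total.

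Of the 210 splits of the 10 horses, 100 were run. The training count of 25 was matched by 1 of these, the real one, and the highest of the others had 11 calls. Among the splits run, a count as high was thus rarer than a share of 0.05. They were run with all 10 horses only, and the count fell to 2 without horse 32 and 1 without horse 33. The splits cannot tell training from anything else that went with the groups. The split with 11 calls exchanged untrained horse 17 with trained horse 31, the horses whose removal raised the count. For sex the real count was 0, so all 90 splits within training group gave as many by construction and they decide nothing. The highest other had 6 calls.

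Trained males 21 and 33 lay apart from the other 8 horses on the first principal component, by 10.2 above the next horse. Depth alone is argued against, since the gap relative to the range kept at least 0.780 of its size in 20 thinnings to the smallest total. Without the 10 most abundant genes, at least 0.822 of the gap was kept in 20 resamplings of genes. The component rests on log2 CPM of 968 genes, so leaving out 10 could hardly have closed the gap. This test therefore cannot decide whether a few abundant genes played a part. Untrained males did not share the shift. Males minus females came to -0.53 in untrained horses, against 16.3 in trained horses, with an SD of 1.35 among untrained horses. The pattern already placed the untrained males among the other 8 horses, so this restates it and is no separate test of sex alone. At equal depth horses 21 and 33 also showed the fewest genes (1738 and 1762), and the quality of their libraries was not tested. A response to training that differs by sex, another mixture of blood cells, handling of the blood and differences between individual horses stay open, since each sex had 2 trained horses and no cell marker could be named.

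One hypothesis was a training response shared by the sexes. With separate horses on both sides, male and female training differences had a Pearson r of 0.392 and a Spearman rho of 0.356 across 968 genes, which are not independent, and the SD over genes was 0.755 in males and 0.449 in females. Of 90 relabellings within sex, 4 gave an r at least as high, the real one included, and the highest of the others was 0.503. This may point to a shared part of the response, but 3 other relabellings did as well, and each sex had 2 trained horses.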
